A study of Homo sapiens with 18 samples.

How the data were processed

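Gene expression was measured in 18 skin biopsies from the edge of venous leg ulcers of 9 patients, 2 biopsies a patient, taken at week 0 and at week 1. Total RNA was labelled with biotin for Affymetrix 3' expression arrays, and 1 array was run per biopsy, per the labels' protocols. RMA and GCRMA, methods that subtract background, normalise between arrays and summarise the probes of a probe set, are named per the submitters' processing notes, with no role, order or version. The deposited values are log2 expression values with 1 row per probe set. The genome build and the annotation behind the table are not given in the sources used here.

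The deposited table held 4957 probe sets and 18 columns, each mapped to 1 sample by its name, and 0 columns were left unmapped. Values ran from -5.97 to 4.98, and the medians of the columns lay between -0.05 and 0.04. An exact 0 stood in 39.0% of the rows, while the median over the 18 columns was 0 in only 0.424% of them. A constant had therefore been subtracted from each probe set, over a set of arrays that is unknown, so that only differences between arrays are left and no expression level. The log scale, the direction and the sample of each column were taken as deposited, and the centring stays unknown in detail. No filter on dim probe sets could be tried, because the brightness of a probe set cannot be read from centred values.

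The table held a selection of probe sets. Computed anew, the paired two-sided p of week 1 against week 0 over the BLCC patients was below 0.05 in all 4957 rows, the largest being 0.05, while the same p over the control patients was below 0.05 in 4.40% of the rows. An array of this kind carries about 54000 probe sets, of which about 2700 would lie below 0.05 by chance. A paired p below 0.005 was found in 543 of the 4957 rows. In the simulation described below it was found in 8.49% to 10.93% of the probe sets kept, with a mean of 9.765%. The share in the data lay just above the highest simulated share. Adjusted p-values within the table are therefore too small for the BLCC change, and the comparison of arms is biased toward it, whereas the control change was not itself selected. To gauge this, 20 simulated data sets of 54000 independent probe sets with no change were passed through the same selection. They kept 2564 to 2763 probe sets, of which 1365 to 1575 passed in the BLCC arm, 13 to 127 passed for the difference between arms and 0 to 11 passed in the control arm. In the control arm 11.9% to 15.1% of those kept had an unadjusted p below 0.05. Independent probe sets give no bound for genes that vary together.

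Probe sets were named through the platform annotation. A single gene symbol was given for 3930 probe sets, several symbols for 185, and 842 were unnamed here. Of the single symbols 3928 matched a gene by its ID and 0 were updated. Probe sets linked to XIST or to the Y chromosome were left out, leaving 4953 for testing, which named 3263 genes, 532 of them by more than 1 probe set. A gene with several probe sets was represented by the one with the highest mean over the 18 samples. This choice was fixed beforehand and is arbitrary on centred values, which hold no level. With the mean of all probe sets of a gene camera called 9, 2 and 6 lists in the BLCC arm, the control arm and the difference, against 8, 2 and 6. In addition, no gene was named from a probe set with several symbols.

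Samples were grouped by arm and week from their titles. The titles give each patient's number within an arm and the design text gives 2 biopsies per patient, which pairs the samples. In the values, deviations from the group means correlated between 0.553 and 0.758 within patients, against a median of -0.08 between patients, and in 9 of 9 patients the week 0 biopsy correlated best with the patient's own week 1 biopsy. The changes within each arm and their difference were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the patient as a fixed block and all 18 samples in 1 fit. The arms at week 0 and at week 1 were compared in a fit of 4 group means with the patient as a random block. The consensus correlation for that block was 0.628, which the selection can also have raised. P-values were adjusted by the Benjamini-Hochberg method over the 4953 probe sets, with a threshold of 0.05.

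Genes were grouped by 32 lists: type I interferon response, interferon gamma response and antigen presentation, inflammatory cytokines and chemokines, neutrophils, monocytes and macrophages, T and NK cells, B and plasma cells, mast cells, Langerhans and dendritic cells, keratinocyte activation, basal keratinocytes, keratinocyte differentiation, cell cycle, Wnt targets, Wnt ligands and receptors, matrix proteins, matrix proteases, growth factors, endothelium, smooth muscle, skeletal muscle, adipocytes, sweat and sebaceous glands, hair keratins, melanocytes, hypoxia, immediate early genes, glucocorticoid targets, cholesterol and fatty acid synthesis, red blood cells, ribosomal proteins and oxidative phosphorylation. The 16 lists with at least 4 genes in the table were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other genes of the table, and again with an estimated correlation. Beside it, the mean change of a list per patient was tested by exact sign flips within an arm (64 for BLCC, smallest p 0.0312, and 8 for control, smallest p 0.25) and by exact reassignment of the patients to arms (84, smallest p 0.0119). No member of the keratinocyte activation list or of the smooth muscle list was analysed here.

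The genes named in the text followed a rule. For each change and for the difference, these were the 10 genes that rose and the 10 that fell most among those past the threshold and, within an arm, of the same sign in every patient. Where fewer than 10 passed, the 8 higher and the 8 lower with the smallest unadjusted p were taken. Up to 4 members of each list with the smallest p and a few fixed genes, of which AXIN2 and IL1B were in the table, were added. These tests, lists, rule and alternatives were set before the data were examined. The adjustment over the whole array and the simulation of the selection were added once the selection had been seen. Tests named below as chosen after the results were also later additions.

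The scripts were tested on simulated data with 4953 unselected probe sets. Of the probe sets changed 1.5-fold, 2-fold and 4-fold in the BLCC arm, 76.1%, 95.5% and 98.5% were recovered, and 4.76% of the calls were false. For the difference between arms the shares were 43.3%, 67.2% and 93.9%, with 3.55% false. The alternatives were other ways of treating the patient, fits on fewer samples, quantile normalisation, centring on the median, 1 probe set per gene, limma's trend and robust options, array weights, other thresholds and the removal of each patient in turn. Plots were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3. The number of arrays, 3 patients in 1 arm and 6 in the other, sets the precision.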

Results

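Expression was compared in 18 biopsies from the non-healing edge of venous leg ulcers, chronic wounds of legs with poor venous return. In the control arm 3 patients received compression bandaging, the standard care. In the other arm 6 patients received the same care with a bioengineered living cell construct (BLCC), a skin substitute made of living keratinocytes and fibroblasts that is laid on the wound. Each patient was biopsied at week 0, on entering an arm, and at week 1. The design asks which genes change at the ulcer edge in the first week of BLCC treatment, whether compression alone gives the same change, and, by the study's title, whether the tissue takes on features of an acute wound. Array data have no read depth, and the number of patients limits the precision.

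The 4953 probe sets tested came from a table in which every probe set had a paired p below 0.05 between the weeks in the BLCC patients. Within this table "rose" and "fell" are used of genes with a limma adjusted p under 0.05, a bar that the selection made easier to pass for the BLCC change. Counts within a gene list are over its members named in the table by a probe set with 1 gene symbol. Other members may be missing through the selection or because no probe set named them alone. Counts adjusted over the list alone use only the p-values of the members in the table. For the BLCC change they give no separate support, because each probe set had been selected on that change. Values are mean log2 changes from week 0 to week 1 with the SD over patients, n = 6 for BLCC and n = 3 for control.

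In the BLCC patients, many of the genes of inflammation and of leukocytes in the table rose and pigment cell genes fell. As lists none of these passed with an estimated correlation between genes (smallest camera adjusted p = 0.162). Among genes of 1 sign in 6 of 6 patients, each read by the probe set chosen for it, the largest rises were those of the collagenase MMP13 (1.72 ± 0.88), the neutrophil chemokine CXCL2 (1.55 ± 1.20) and the macrophage chemokine CCL18 (1.42 ± 0.57). FAM13C (1.37 ± 0.52), TENT5C (1.35 ± 1.26), PRND (1.19 ± 0.93), KLHL6 (1.14 ± 0.50), the lipoprotein-associated phospholipase PLA2G7 (1.12 ± 0.55), the apelin receptor APLNR of endothelial cells (1.08 ± 0.80) and CYTL1 (1.08 ± 0.52) followed. The largest falls in this set were those of the melanosome genes TYRP1 (-2.47 ± 1.42), MLANA (-1.73 ± 1.00) and PMEL (-1.68 ± 0.72). They were followed by the thyroid hormone deiodinase DIO2 (-1.47 ± 1.17), the mucin-like FCGBP (-1.42 ± 1.00) and the melanocyte channel TRPM1 (-1.35 ± 0.63). The cornified layer adhesion protein CDSN (-1.32 ± 1.14), BTG3 (-1.29 ± 1.12), the natriuretic peptide receptor NPR3 (-1.29 ± 0.70) and the carnitine synthesis enzyme BBOX1 (-1.27 ± 1.13) came after them. Outside this set, IL1B (1.43 ± 1.27), CASP14 (-1.45 ± 0.87), SLC1A6 (-1.97 ± 0.31) and RARRES1 (1.48 ± 0.87), the last 2 by a probe set that was not the chosen one, changed by as much and were noted after their values were seen. In all, 1825 probe sets rose and 1516 fell, 3341 together, with a median change of 0.27 in size over the table.

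Part of that count comes from the selection. Simulated arrays with no change, selected alike, kept 2564 to 2763 probe sets and gave 1365 to 1575 calls. These were 51.3% to 57% of the probe sets kept, to be set against 3341 of 4953 in the data. Without the patient as a block limma called 0, with 1417 at an unadjusted p below 0.05. With the adjustment taken over the whole array of about 54000 probe sets, added after the selection was seen, 20 probe sets passed, 14 higher and 6 lower, against 0 or 1 in each simulated data set. That adjustment changed only the number of tests, and the p-values still came from a limma fit to the selected probe sets. In these the median SD of the change was 0.20 in BLCC and 0.26 in control patients. The simulated probe sets were independent, so they give no bound for genes that vary together. The count of 20 against 0 or 1 therefore does not exclude chance. With the paired p of each probe set alone, without limma's shared variance, the smallest p adjusted over the array was 0.349. Among the higher of the 20 were the leukocyte genes CTSS (0.95 ± 0.35), CYTIP (0.98 ± 0.28), EVI2B (0.87 ± 0.20), NCF4 (0.60 ± 0.14), the complement receptor C5AR1 (1.06 ± 0.38), P2RY8 (0.69 ± 0.21) and APOBEC3G (0.73 ± 0.25). The endothelial and leukocyte adhesion molecule ICAM2 (0.67 ± 0.20), FAM13C, C16orf54, ST8SIA4, C3orf80 and TMEM71 were also higher. Among the lower were PMEL, MLANA (-1.88 ± 0.85), the glutamate transporter SLC1A6 by both of its probe sets (-1.97 ± 0.31 and -1.18 ± 0.34) and REL (-0.85 ± 0.36). NCF4 and MLANA passed by a probe set that was not the chosen one, and the chosen ones did not pass (limma p adjusted over the array 0.056 and 0.0669). These were named because they passed, after their values were seen.

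**Figure D1:**
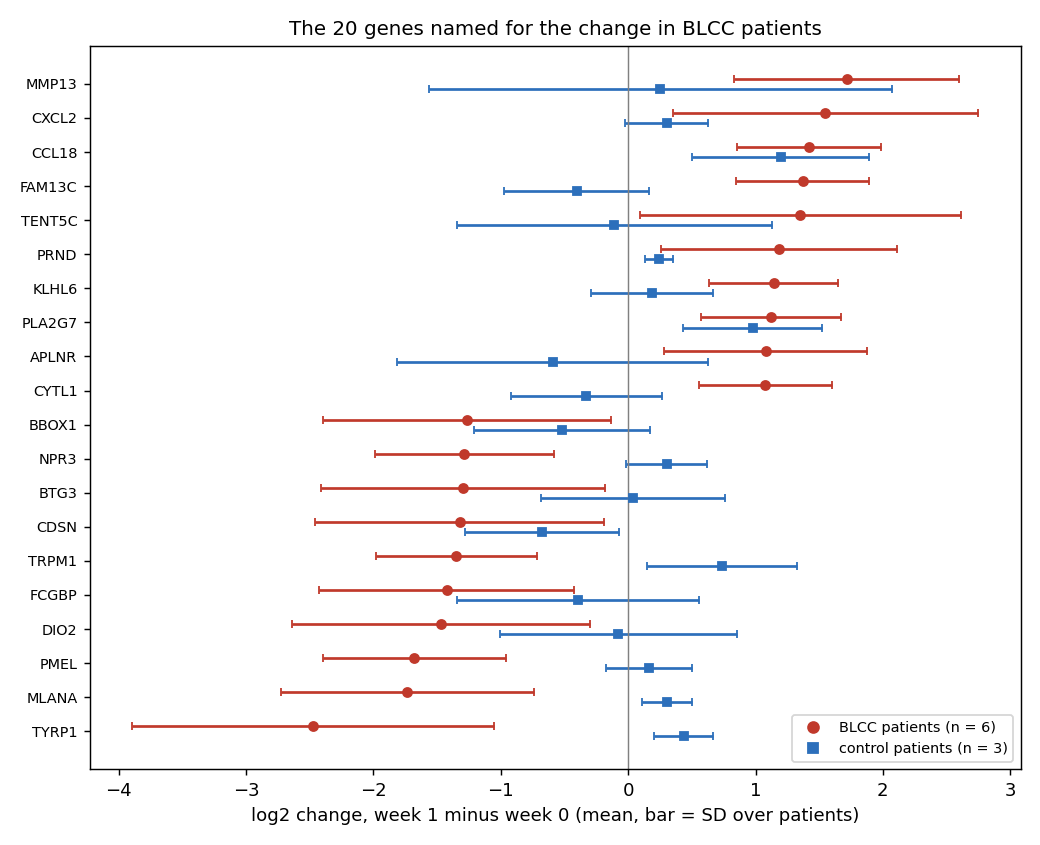
Mean log2 change from week 0 to week 1 (horizontal axis) of the 20 genes named for the BLCC change, with bars of 1 SD over patients, in BLCC patients (circles, n = 6) and control patients (squares, n = 3). TYRP1 was at -2.47 in BLCC and 0.44 in control patients, whereas CCL18 was at 1.42 and 1.20.

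Of the 16 gene lists tested, 7 shifted up and 1 shifted down in the BLCC patients by camera. With an estimated correlation between genes none of the 8 passed, the smallest adjusted p being 0.162. Over these 8 lists the estimates ran from 0.017 for matrix proteases to 0.818 for macrophage markers. The lowest lay near the preset 0.01 and its call was lost too, so the size of the correlation alone does not explain that loss. The sign of the list mean was the same in 6 of 6 patients for 13 of the 16 lists (exact adjusted p = 0.0385). That gives no separate support, because the probe sets were selected on these patients: with no change, 52.9% of the simulated probe sets kept had 1 sign in all 6. By camera with the preset correlation, 3 of the 32 ways of swapping the week labels within patients gave as many lists, the real labels included.

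Of 34 inflammatory cytokines and chemokines 7 were in the table, and all 7 rose, 7 of 7 adjusted over the list alone, with a mean change of 1.11 ± 0.42 (adjusted p = 0.00357, and adjusted p = 0.162 with an estimated correlation). Beside CXCL2 and CCL18 these included the interleukin IL1B (1.43 ± 1.27, higher in 5 of 6 patients), CXCL3 (1.01 ± 0.63) and the anti-inflammatory IL10 (0.68 ± 0.40). Of 18 monocyte and macrophage markers 15 rose, also 15 adjusted over the list alone, with a mean of 0.69 ± 0.40 (adjusted p = 0.000533, and adjusted p = 0.435 with an estimated correlation). Examples were MS4A4A (1.05 ± 0.53), the lysosomal LAPTM5 (0.82 ± 0.44), the chemokine receptor CCR1 (0.76 ± 0.41) and the costimulator CD86 (0.74 ± 0.44). Of 7 neutrophil markers 5 rose, 6 adjusted over the list alone, with a mean of 0.54 ± 0.21 (adjusted p = 0.0258, and adjusted p = 0.435 with an estimated correlation), among them the Fc receptor FCGR3B (0.80 ± 0.68) and the formyl peptide receptor FPR1 (0.73 ± 0.54).

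The interferon gamma and antigen presentation list shifted up by 0.53 ± 0.26 (adjusted p = 0.00302, and adjusted p = 0.406 with an estimated correlation). Of its 12 genes 11 rose, 11 adjusted over the list alone. Those with the smallest p were the guanylate binding protein GBP5 (0.92 ± 0.52) and the class II genes HLA-DRA (0.80 ± 0.50), HLA-DMA (0.74 ± 0.36) and HLA-DPB1 (0.57 ± 0.35). Of 10 T and NK cell markers 8 rose, 9 adjusted over the list alone, with a mean of 0.53 ± 0.27 (adjusted p = 0.00879, and adjusted p = 0.435 with an estimated correlation). These included the costimulatory receptor CD28 (0.93 ± 0.46), the lymphocyte transcription factor IKZF1 (0.78 ± 0.28) and the interleukin 2 receptor chain IL2RB (0.66 ± 0.45). In the B and plasma cell list 3 of 5 genes rose, 3 adjusted over the list alone, with a mean of 0.43 ± 0.10, and camera did not pass (adjusted p = 0.294). IGHM (0.89 ± 0.18), IRF4 (0.62 ± 0.50) and IGKC (0.59 ± 0.34) were its members that rose.

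Endothelial markers shifted up by 0.57 ± 0.27 (adjusted p = 0.0194, and adjusted p = 0.435 with an estimated correlation), with 6 of 8 rising and 7 adjusted over the list alone. The smallest p-values among them were those of the VEGF receptor KDR (0.84 ± 0.48), the angiopoietin receptor TEK (0.63 ± 0.47), the transcription factor SOX17 (0.62 ± 0.47) and CLEC14A (0.56 ± 0.37). Matrix proteases and their inhibitors shifted up by 0.56 ± 0.18 (adjusted p = 0.00565, and adjusted p = 0.162 with an estimated correlation), with 9 of 11 rising, 9 adjusted over the list alone. Beside MMP13 and cathepsin S (CTSS) these included the plasminogen activator PLAT (0.63 ± 0.43) and the urokinase receptor PLAUR (0.50 ± 0.41). Growth factors and receptors went both ways, 5 rising and 5 falling of 11 (6 and 5 adjusted over the list alone), and camera did not call the list (mean 0.09 ± 0.07, adjusted p = 0.72). KDR, VEGFC (0.73 ± 0.41) and CSF1 (0.38 ± 0.24) rose while ERBB3 (-0.95 ± 0.87) fell.

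Melanocyte markers shifted down by -1.24 ± 0.51 (adjusted p = 0.000221, and adjusted p = 0.224 with an estimated correlation), and 8 of 8 fell, 8 adjusted over the list alone. Beside TYRP1, MLANA, PMEL and TRPM1 these were the pigment enzyme TYR (-1.22 ± 0.58), OCA2 (-0.56 ± 0.41), GPR143 (-0.54 ± 0.25) and KIT (-0.36 ± 0.26), which mast cells also express. The 6 keratinocyte genes in the table fell as well: the cornification protease CASP14 (-1.45 ± 0.87), CDSN, the lipoxygenase ALOXE3 (-0.33 ± 0.29), the hemidesmosome integrin ITGB4 (-0.59 ± 0.49), the laminin chain LAMB3 (-0.58 ± 0.54) and EGFR (-0.20 ± 0.15). Of 3 matrix genes FBLN1 (0.84 ± 0.75) and COL6A1 (0.83 ± 0.78, 3 of 4 probe sets of the same sign) rose, and COL14A1 was at 0.29 ± 0.18. The Langerhans cell lectin CD207 (-1.24 ± 0.82) and FCGBP fell while the dendritic cell genes CD83 (0.43 ± 0.34) and CLEC4A (0.63 ± 0.34) rose, each also adjusted over the list alone. Camera did not call their list (mean -0.40 ± 0.43, adjusted p = 0.785).

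Ribosomal protein genes had a mean of -0.12 ± 0.06 (adjusted p = 0.054), with 2 of 11 falling and 1 adjusted over the list alone, led by RPL37 (-0.33 ± 0.15). Wnt and beta-catenin targets had a mean of -0.18 ± 0.12 (adjusted p = 0.328). RNF43 (-0.47 ± 0.30) and FGFR2 (-0.22 ± 0.15) fell, 1 of them adjusted over the list alone, while the feedback inhibitor AXIN2 was at -0.22 ± 0.18 (adjusted p = 0.114). Wnt ligands, receptors and antagonists had a mean of -0.0088 ± 0.07 (adjusted p = 0.802), with DKK3 (0.33 ± 0.27) and APC (0.24 ± 0.18) rising and LRP6 (-0.24 ± 0.08) and GSK3B (-0.29 ± 0.23) falling, 4 adjusted over the list alone. Its member DKK2 was at 0.07 by the probe set used and at -1.18 by another. Glucocorticoid targets had a mean of 0.10 ± 0.13 (adjusted p = 0.597), with glutamine synthetase GLUL (0.61 ± 0.35) and CDKN1C (0.48 ± 0.43) rising and HSD11B2 (-0.53 ± 0.39) falling, 3 higher and 2 lower adjusted over the list alone. Sweat and sebaceous gland markers had a mean of -0.12 ± 0.07 (adjusted p = 0.453), with the sterol acyltransferase SOAT1 (0.67 ± 0.48) rising and KRT8 (-0.22 ± 0.13) falling, both also adjusted over the list alone.

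**Figure D2:**
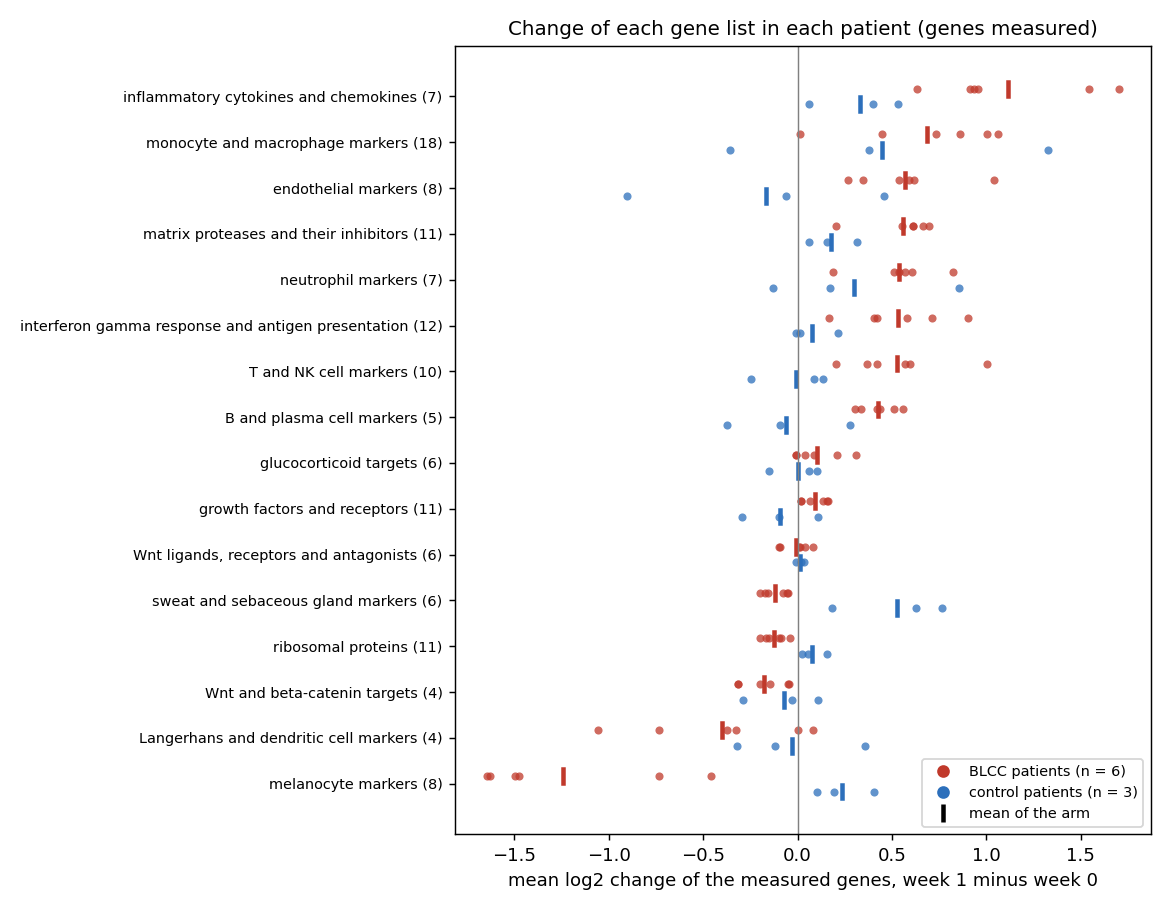
Mean log2 change of the genes of each list in the table (horizontal axis) in each BLCC patient (n = 6) and each control patient (n = 3), with dashes for the mean of the arm and the number of genes in parentheses. Melanocyte markers averaged -1.24 in BLCC and 0.23 in control patients, and macrophage markers 0.69 and 0.45.

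In the control patients no single gene passed. The mean of the macrophage list was above 0 in 2 of 3 patients, a call that was lost with an estimated correlation (adjusted p = 0.66), and the chemokine CCL18 was at 1.20. For the control change limma called 0 probe sets, with 543 at an unadjusted p below 0.05 and a smallest adjusted p of 0.246. These 543 were 11.0% of the probe sets, where simulated arrays with no change, selected alike, had 11.9% to 15.1%. In a fit of the control samples alone 0 passed and 246 had an unadjusted p below 0.05. The genes with the smallest p among those of 1 sign in all 3 patients were, among the higher, IL10 (0.96 ± 0.04), PARD6B (0.44 ± 0.19), NPAS4 (0.50 ± 0.30), SYNE3 (0.47 ± 0.27), CCL18 (SD 0.70), the muscle ubiquitin ligase TRIM63 (0.69 ± 0.49), CSHL1 (0.47 ± 0.33) and GSTO1 (0.43 ± 0.24). Among the lower they were the dynein heavy chain DYNC1H1 (-0.62 ± 0.19), ABHD16A (-0.58 ± 0.23), C3orf80 (-0.69 ± 0.34), the clock gene PER3 (-0.55 ± 0.09), DGLUCY (-0.58 ± 0.29), CNOT4 (-0.61 ± 0.15), CCDC102B (-0.80 ± 0.48) and POU2F2 (-0.42 ± 0.17).

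By camera 2 lists shifted in the control arm, both up. Monocyte and macrophage markers had a mean of 0.45 ± 0.84 (adjusted p = 0.000386, and adjusted p = 0.66 with an estimated correlation), with 17 of 18 genes higher, MS4A4A at 0.83 ± 1.07 and LYZ at 0.72 ± 0.95. Without control replicate 1 the mean was 0.01 and the call was lost. Sweat and sebaceous gland markers had a mean of 0.52 ± 0.30 (adjusted p = 0.0035, and adjusted p = 0.139 with an estimated correlation) and were higher in 3 of 3 patients. SOAT1 (0.72 ± 0.23) had the smallest p, while CA6 (0.94 ± 1.28) and THRSP (0.76 ± 1.58) had larger changes. The call of the gland list was lost without control replicate 2 (mean 0.40) and without control replicate 3 (mean 0.47). Adjusted over the list alone, IL10 and CCL18 passed in the inflammatory list and 1 gene in the gland list, and 0 genes in the other tested lists. In lists too small to test, KIT of the mast cell list (0.42 ± 0.21) and BIRC5 of the cell cycle list (0.58 ± 0.63) passed adjusted over the list alone. These lists had only 2 and 3 genes in the table. Over the melanocyte list KIT did not pass (limma adjusted p = 0.0869), and over all probe sets neither gene passed (limma adjusted p = 0.349 and 0.335). With 3 patients the exact sign-flip p cannot go below 0.25, which was the value for the gland list, and it was 0.50 for the macrophage list.

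The other lists did not pass in the control arm with all 3 patients. Inflammatory cytokines had a mean of 0.33 ± 0.25 (adjusted p = 0.104), neutrophil markers 0.30 ± 0.50 (adjusted p = 0.104) and matrix proteases 0.18 ± 0.13 (adjusted p = 0.104). Melanocyte markers were at 0.23 ± 0.16 (adjusted p = 0.238), ribosomal proteins at 0.08 ± 0.07 (adjusted p = 0.137), interferon gamma genes at 0.07 ± 0.12, T and NK cell markers at -0.0073 ± 0.21 and endothelial markers at -0.17 ± 0.69. Neutrophil markers passed without control replicate 3 (0.51, adjusted p = 0.0173). Endothelial markers passed downward without control replicate 2 (-0.48, adjusted p = 0.0227) and were at 0.20 without control replicate 1. The remaining lists lay between -0.09 for growth factors and 0.02 for Wnt ligands, with the glucocorticoid mean at 0.0046 and its median at -0.09. The Langerhans list had a mean of -0.03 although camera ranked it upward (adjusted p = 0.875).

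**Figure D3:**
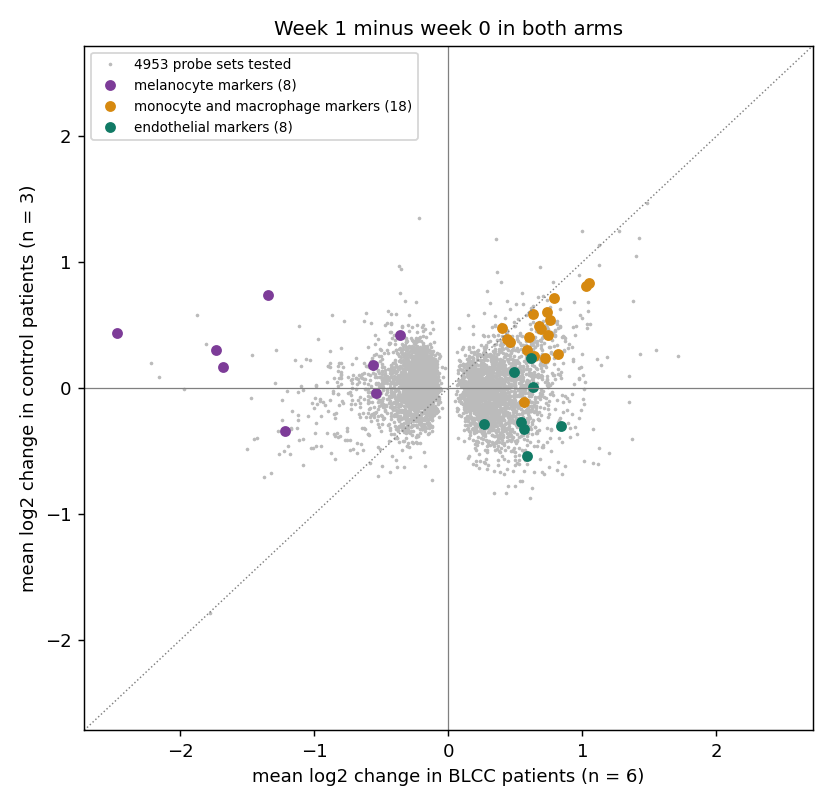
Mean log2 change from week 0 to week 1 of 4953 probe sets in BLCC patients (horizontal axis, n = 6) and control patients (vertical axis, n = 3), with the members of 3 gene lists coloured and a dotted line of equal change. The empty band around 0 on the horizontal axis comes from the selection of the table, and the changes of the arms correlated at 0.018 across probe sets, which are not independent.

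The difference between the arms, BLCC change minus control change, was largest for melanocyte markers among the 16 lists. Single genes are again read by 1 probe set each. TYRP1 (-2.91), TRPM1 (-2.09), MLANA (-2.04) and PMEL (-1.85) fell relative to the control arm. So did NPR3 (-1.59), VAV3 (-1.36), the amino acid transporter SLC6A15 (-1.34), FAM83B (-1.31), WFDC21P (-1.16) and STON2 (-1.10). FAM13C (1.78), the mesenchymal homeobox gene MEOX2 (1.53), the noncoding RNA MIAT (1.49), CCDC102B (1.42) and CYTL1 (1.40) rose relative to it. So did C3orf80 (1.40), FUT8-AS1 (1.38), the vascular potassium channel KCNJ8 (1.30), the transcription factor EBF1 (1.28) and PTP4A3 (1.26). For CCDC102B and C3orf80 the control change was at -0.80 ± 0.48 and -0.69 ± 0.34, and for SLC6A15 the BLCC change was only -0.37 ± 0.21. In all 536 probe sets passed, 336 higher and 200 lower. In contrast, CCL18 (0.22, adjusted p = 0.621) and PLA2G7 (0.14, adjusted p = 0.729) differed by less than the spread between patients. MMP13 (1.46, limma adjusted p = 0.144) and CXCL2 (1.25, limma adjusted p = 0.142), the largest rises named for the BLCC patients, did not pass either. Nor did FCGBP (-1.03, limma adjusted p = 0.188) and CDSN (-0.65, limma adjusted p = 0.392). The count of 536 became 0 without the block, 0 with array weights, 25 after quantile normalisation, 4 without BLCC replicate 4 and 11 without control replicate 1. Simulated arrays with no change, selected alike, gave 13 to 127 from fewer probe sets. These were 0.482% to 4.77% of the probe sets kept, to be set against 536 of 4953 in the data.

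By camera 6 lists differed in their shift, none with an estimated correlation, and 3 of the 6 also passed the exact reassignment test. That test gives no separate support, because the probe sets were selected on the BLCC change, which favours the real arms. Melanocyte markers differed by -1.47 ± 0.28 (SE, adjusted p = 7.22e-05, and adjusted p = 0.305 with an estimated correlation, exact adjusted p = 0.0476). Of its 8 genes 5 fell, KIT at -0.78 among them, and 8 passed adjusted over the list alone. Endothelial markers differed by 0.74 ± 0.27 (SE, adjusted p = 0.0231, and adjusted p = 0.41 with an estimated correlation, exact adjusted p = 0.0714), with KDR (1.15) rising and 2 genes adjusted over the list alone. Without control replicate 1 that difference was 0.37 (adjusted p = 0.2). T and NK cell markers differed by 0.53 ± 0.17 (SE, adjusted p = 0.0231, and adjusted p = 0.393 with an estimated correlation, exact adjusted p = 0.0635). IL2RB (1.02) and IKZF1 (0.84) rose, and 4 genes passed adjusted over the list alone. Interferon gamma genes differed by 0.46 ± 0.15 (SE, adjusted p = 0.0231, and adjusted p = 0.393 with an estimated correlation, exact adjusted p = 0.0714). GBP5 (1.13), HLA-F (0.91) and IRF1 (0.76) rose, and 4 genes in all passed adjusted over the list alone. Both of these calls were lost without control replicate 2 (differences 0.42 and 0.43), and the second also without control replicate 3 (0.42).

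Sweat and sebaceous gland markers differed by -0.64 ± 0.12 (SE, adjusted p = 0.0343, and adjusted p = 0.305 with an estimated correlation, exact adjusted p = 0.0476), with none of 6 genes passing and 2 adjusted over the list alone. This call was lost without control replicate 2 (-0.52), control replicate 3 (-0.59) or BLCC replicate 1 (-0.63). Ribosomal proteins differed by -0.20 ± 0.07 (SE, adjusted p = 0.0231, and adjusted p = 0.393 with an estimated correlation, exact adjusted p = 0.0476), with none of 11 passing and 0 adjusted over the list alone. It was lost without control replicate 1 (-0.16). Macrophage markers differed by 0.24 ± 0.35 (SE, adjusted p = 0.339, exact adjusted p = 0.61), at 0.68 without control replicate 1, where the call was gained (adjusted p = 0.000827), and -0.16 without control replicate 3. Neutrophil markers differed by 0.24 (adjusted p = 0.417), inflammatory cytokines by 0.78 (adjusted p = 0.168), matrix proteases by 0.38 (adjusted p = 0.168) and B and plasma cell markers by 0.49 (adjusted p = 0.191, exact adjusted p = 0.0476). Growth factors differed by 0.19 (adjusted p = 0.415), with KDR, PDGFRB (0.70) and CSF1 (0.57) rising and 3 genes adjusted over the list alone. The Langerhans (-0.37), Wnt target (-0.11), Wnt ligand (-0.02) and glucocorticoid (0.10) lists did not pass, and among them 2 Wnt targets passed adjusted over the list alone.

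**Figure D4:**
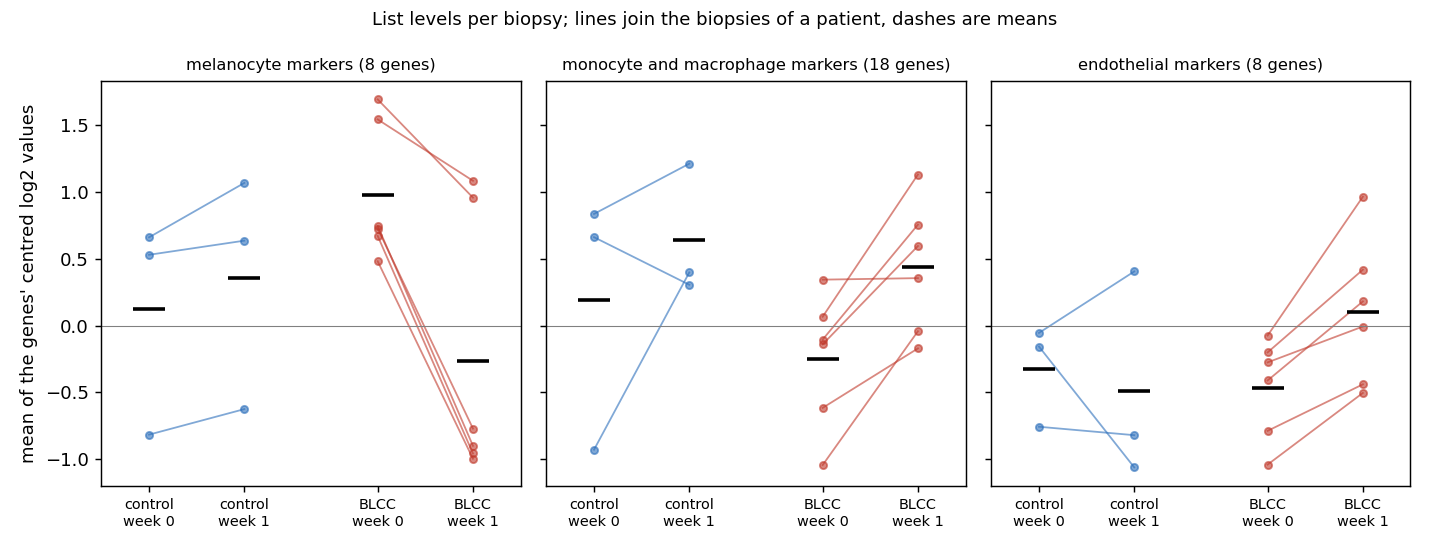
Mean centred log2 value (vertical axis) of the melanocyte, macrophage and endothelial lists in each biopsy, with lines joining the biopsies of a patient and dashes for the group means. The melanocyte mean went from 0.98 to -0.26 in BLCC patients (n = 6) and from 0.12 to 0.36 in control patients (n = 3).

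Between the arms, melanocyte markers lay higher in BLCC than in control patients at week 0, by 0.85 (exact reassignment p = 0.0952), and lower at week 1, by -0.62 (exact p = 0.333). Without control replicate 1 these gaps were 0.38 and -1.11 (exact p = 0.321 and 0.393), and without control replicate 2 they were 1.12 and -0.27 (exact p = 0.107 and 0.786), computed after the levels were seen. B and plasma cell markers were lower in BLCC patients at week 0 by -0.63 (exact p = 0.0476, unadjusted over the lists). No probe set passed at either time. At week 0 limma called 0, with 467 at an unadjusted p below 0.05 and a smallest adjusted p of 0.478. At week 1 it called 0, with 439 and 0.153. Fits of the biopsies of 1 week alone also called 0, with 478 and 390 at an unadjusted p below 0.05. The selection can pull the arms apart at both weeks, in opposite directions for rising and falling genes, and only week 0 was simulated. A score took the mean of the probe sets higher at week 1 in BLCC patients minus that of the lower ones. At week 0 it averaged -0.36 in BLCC and 0.04 in control patients (exact reassignment p = 0.0357, which the selection can lower). In simulated arrays with no change, selected alike, the gap was narrower, -0.27 to -0.22. Their probe sets were independent, which gives no bound for genes that vary together.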

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

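The tests of epidermal share, of dermal share and of a rise common to both arms, and the label swaps for the gene counts within each arm and at each week, and the removal of single patients from the melanocyte levels, were chosen only after the results were seen.

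In 3 of 38 groups of 6 BLCC patients, 1 patient stood apart from the rest by Dixon's test, where chance gives about 1 in 20. The gap was 0.704 of the range for the change of the matrix protease list, 0.69 for TENT5C and 0.675 for PMEL.

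The change differed between arms for 536 probe sets and for 6 lists, with differences of 0.46 for interferon gamma genes, 0.53 for T and NK cell markers, 0.74 for endothelial markers, -0.64 for gland markers, -1.47 for melanocyte markers and -0.20 for ribosomal proteins. None of these 6 passed with an estimated correlation, the adjusted p running from 0.305 to 0.41. Among genes past the threshold, each read by the probe set chosen for it, the widest differences were those of FAM13C (1.78), MEOX2 (1.53), MIAT (1.49), CCDC102B (1.42), CYTL1 (1.40), C3orf80 (1.40), FUT8-AS1 (1.38), KCNJ8 (1.30), EBF1 (1.28) and PTP4A3 (1.26) above, and TYRP1 (-2.91), TRPM1 (-2.09), MLANA (-2.04), PMEL (-1.85), NPR3 (-1.59), VAV3 (-1.36), SLC6A15 (-1.34), FAM83B (-1.31), WFDC21P (-1.16) and STON2 (-1.10) below.

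Other splits of the samples were compared with the real one. For the BLCC change, 1 of 32 swaps of the week labels within patients, the real labels, called as many probe sets (3341, highest other 0), and for the difference between arms 1 of 84 reassignments of the patients (536, highest other 16). Neither excludes chance, because the probe sets had been selected on the real labels. For the control arm the 4 swaps are too few for a share under 0.05, with 0 probe sets against 0 and 2 lists against 2 (3 of 4 swaps gave as many lists). Between the arms at week 0 and at week 1 the real count was 0. All 84 of 84 reassignments therefore had to call at least as many, which decides nothing. The highest others were 3 and 64. For the lists chance was not excluded: 3 of 32 swaps gave at least the 8 lists of the BLCC change (highest other 9), and 7 of 84 reassignments gave at least the 6 lists of the difference (highest other 7).

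Melanocyte markers fell in the BLCC patients by -1.24 ± 0.51 and were at 0.23 ± 0.16 in control patients. A smaller share of epidermis in the week 1 biopsies cannot be told apart from a change of melanocytes: the 6 keratinocyte genes in the table were all lower, with a mean of -0.74 ± 0.46 in BLCC patients and -0.29 ± 0.46 in control patients, but they are 6 of 63 list members, kept because they changed in these patients. The melanocyte change minus the keratinocyte change was -0.50 ± 0.52 in BLCC and 0.52 ± 0.36 in control patients. Its exact sign-flip p in BLCC patients was 0.0312, the smallest possible, but both sets of genes had been selected in these patients. Over the 6 BLCC patients the correlation of the changes gave no decision (Pearson r = 0.433, exact permutation p = 0.378, Spearman correlation 0.314, exact permutation p = 0.564, r = 0.884 without the 2 patients farthest from the median, 1 relation computed). A high level before treatment that returned to the control level cannot be told apart from a fall below it, since BLCC patients lay above control patients by 0.85 at week 0 (exact p = 0.0952) and differed by -0.62 at week 1 (exact p = 0.333), gaps that were 0.38 and -1.11 without control replicate 1 (exact p = 0.321 and 0.393) and 1.12 and -0.27 without control replicate 2. Fewer melanocytes or less pigment gene expression under BLCC stays open as a hypothesis.

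The macrophage, neutrophil, T and NK cell and endothelial lists shifted up in the BLCC patients by camera, and none did with an estimated correlation (adjusted p = 0.435). A larger share of dermis in the week 1 biopsies cannot be told apart from this: the 3 matrix genes in the table had a mean of 0.65 ± 0.45 in BLCC patients and -0.15 ± 0.58 in control patients (exact p of the difference = 0.0595), but they are 3 of 40 list members, kept because they changed in these patients. None of 18 smooth muscle and pericyte markers was named in the table by a probe set with 1 gene symbol. Members missing from it, through the selection or the annotation, decide nothing. A rise common to both arms cannot be told apart from an effect of BLCC: the control means were 0.45 ± 0.84 for macrophage markers (exact p of the difference = 0.571, with a control mean of 0.01 and a difference of 0.68 at adjusted p = 0.000827 without control replicate 1, and a difference of -0.16 without control replicate 3), -0.0073 ± 0.21 for T and NK cell markers (exact p = 0.0238, adjusted p = 0.0635) and -0.17 ± 0.69 for endothelial markers (exact p = 0.0357, adjusted p = 0.0714), and the last 2 are too small because probe sets were selected on the BLCC change. Influx of leukocytes and growth of vessels under BLCC are biological explanations that stay open, untested by any other measure.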

How the results depend on the processing

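The adjustment over the whole array was chosen after seeing the data. Of the results compared, 0 reversed direction at a called value. The count of 3341 for the BLCC change fell to 0 without the patient block (1417 at an unadjusted p below 0.05), to 2171 with 1 probe set per gene, where fewer rows were tested, to 554 at 1.5-fold or more and to 20 over the whole array, and other settings gave 2394 to 4456. For the difference between arms 536 became 0 without the block (554 at an unadjusted p below 0.05), 0 with array weights (1305), 0 over the whole array (1912), 25 after quantile normalisation, 326 with 1 probe set per gene and 1476 at an adjusted p below 0.10. Centring arrays on their medians gave 424 higher and 150 lower, against 336 and 200. Without the block the list counts and the 0 of the other comparisons stayed the same. For the control change a random block called 3 and other settings 0, with 106 to 584 at an unadjusted p below 0.05. With an estimated correlation 0 lists passed in the BLCC arm, 0 in the control arm and 0 for the difference, where the exact tests passed 13, 0 and 4. Leaving out 1 patient at a time gave 1818 to 3829 probe sets for the BLCC change, with 2074, 1818, 1823 and 2185 without BLCC replicates 3, 4, 5 and 6. It gave 0 to 1 for the control change (1 without control replicate 2 or BLCC replicate 4), 0 to 1 at week 0 (1 without control replicate 2) and 0 to 4 at week 1 (4 without control replicate 2, 1 without control replicate 3). For the difference it gave 4 to 496: 11, 324 and 231 without control replicates 1, 2 and 3, and 143, 148, 4, 144 and 92 without BLCC replicates 2 to 6. Lists numbered 8 to 9 in the BLCC arm, 1 to 2 in the control arm (1 without control replicate 1) and 3 to 6 for the difference (3 without control replicate 2). The causes were not tested. For named genes under other settings 2911 values kept direction and side of the threshold, 343 lost the call, 89 gained it and 5 uncalled values changed sign, and for list means the numbers were 207, 21, 7 and 5. With 1 patient left out they were 2496, 254, 39 and 37 for named genes and 403, 11, 6 and 12 for list means. A filter on dim probe sets was not run, because centred values hold no signal over background, and what the brightness of the probe sets limits is unknown.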

Other observations

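The test of rows passing together was chosen only after the result was seen.

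Lists with fewer than 4 genes in the table were not tested as lists. In the BLCC patients the flow-responsive endothelial factor KLF2, the only one of 30 immediate early genes in the table, rose by 0.73 ± 0.22, against -0.12 ± 0.58 in control patients, and the difference of 0.85 passed (adjusted p = 0.0427). The glucose transporter SLC2A3 rose (0.63 ± 0.50) and the demethylase KDM3A fell (-0.26 ± 0.16), both of the hypoxia list. The interferon genes ISG20 (0.46 ± 0.42) and SP110 (0.26 ± 0.23) rose, and these were 2 of the 41 members of the type I interferon list. Of the lipid synthesis genes INSIG1 rose (0.60 ± 0.52) and ACACA fell (-0.29 ± 0.26). The hair keratin KRT73 (-0.89 ± 0.60), the muscle genes NEB (-0.85 ± 0.65) and TNNC1 (-0.35 ± 0.21) and, of the mast cell list, KIT fell, while GATA2 was at -0.16 ± 0.12. The cell cycle genes BUB1 (-0.19 ± 0.08), TYMS (-0.17 ± 0.15) and BIRC5 (0.14 ± 0.13) did not pass. Nor did the adipocyte genes FABP4 (-0.22 ± 0.20), THRSP (-0.36 ± 0.30) and GPD1 (0.19 ± 0.16, by 1 of its 2 probe sets), the red cell enzyme ALAS2 (-0.20 ± 0.15) and the ATP synthase subunit ATP5PB (0.30 ± 0.26).

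The table held more of some gene lists than of others. Of 30 macrophage markers 18 were in it, 60.0% against 15.9% of the members of other lists (Fisher exact p = 1.13e-07). The melanocyte (50.0%, adjusted p = 0.0275) and interferon gamma lists (38.7%, adjusted p = 0.0467) were also over-represented, whereas 0 of 35 keratinocyte activation genes were in it (adjusted p = 0.0275). The macrophage share argues against probe sets that passed the selection independently by chance as the source of the macrophage members. Genes that vary together may still have passed together by chance, which cannot be told apart from a response because only selected rows were analysed here. The table held 1.83 times the rows expected by chance over the array. Genes are not independent replicates, and the shares depend on the rows analysed here.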
